A study of Mus musculus with 6 samples.

How the data were processed

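Polyadenylated RNA was sequenced from mouse pro-B cells. Fetal liver cells lacking Ebf1 had been transduced with wild-type EBF1 or with an altered form that the labels call dC or YmA, cultured for 8 days, and 50000 cells positive for CD19 were sorted per sample. The groups EBF1_wt, EBF1_dC and EBF1_YmA had 2 libraries each, and all 6 libraries entered every fit. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

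The authors deposited a table of raw counts per gene for the 6 libraries, which held whole numbers and no normalization. Per the submitters' processing notes, STAR, SAMtools, deepTools, featureCounts, Subread 2.0.0 and DESeq2 were used with the builds mm10 and GRCm38.p4. The role and settings of each tool, the strandedness of the counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. The authors also deposited a table of comparisons for 11766 genes. Per the file headers it holds DESeq2's baseMean (a mean of normalized counts), log2 fold changes with standard errors, a Wald statistic (a score with no fixed range), p-values and adjusted p-values. Its header names no reference group. Across genes its log2 fold changes correlated best with those computed here against EBF1_wt (Pearson's r 0.967 for dC and 0.959 for YmA, against 0.471 and 0.023 with the other altered form as reference), so EBF1_wt was taken as the reference. That table was used only for comparison and is named wherever its values are printed.

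Total counts ran from 40423508 to 51283126 per library. No pair of libraries held identical values, and replicates of each group differed by more than sampling noise (chi-square per degree of freedom 236, 184 and 121 for wt, dC and YmA). The count table lists 47937 genes by versioned Ensembl identifier. A gene name was found for 98.51% of them, for 47224 in the reference table and for a further 26 in the authors' deposited table. Positions, GC content and exon length came from the GENCODE M21 annotation of GRCm38 and were found for 14816 of the 14872 tested genes (99.62%).

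Genes with low counts were removed with edgeR's filterByExpr, libraries were scaled with TMM, and edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was fitted with a coefficient per group. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Every adjusted p printed for a gene comes from this test unless another tool is named. Levels are read counts scaled to a common library total after TMM (CPM), with the SD over the 2 libraries of a group. A log2 fold change against a group at 0 counts depends on the prior count, so a bound is given instead, computed against a floor of 3 counts over the group. This bound and every floor cover counting error only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

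The groups share replicate numbers. The labels state no pairing of the samples by these numbers, and only the values point to one. Deviations from the group means correlated between libraries of the same number, all above 0.1. The values were 0.519 for wt and dC, 0.446 for wt and YmA and 0.603 for dC and YmA. In a group of 2 libraries the deviations of replicate 2 mirror those of replicate 1, so each pair of groups gives a single value. The pairing therefore rests on few values, and the fit with the block assumes it. The design fixed in advance had no block, and the fit with the replicate number as a block was listed in advance as an alternative setting. Both are printed where they differ. The biological coefficient of variation was 0.412 without the block and 0.216 with it.

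EdgeR's test of single genes was run on simulated counts, with 50 genes changed at each fold and the shift between replicate numbers kept. The changed genes had a mean of at least 2 log2 CPM. List tests, overlaps and other tools were not part of this simulation. For dC against wt, over 14189 simulated genes, the fit without the block called 0%, 34%, 80% and 82% of the genes changed by 2-fold, 4-fold, 8-fold and 16-fold and 0 unchanged genes. With the block it called 34%, 84%, 100% and 100%, and 9 unchanged genes. In counts simulated without that shift the block did worse: without it 6%, 46%, 84% and 86% were called with 5 unchanged genes, and with it 2%, 28%, 72% and 78% with 6. In the data the fit without the block called 0 of 14872 genes for dC against wt, and Ttll11 at 187-fold was not called. The simulated shares therefore need not hold for the data.

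The tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named Ebf1 and Cd19 in every comparison, up to 10 rises and 10 falls per comparison with wt (5 and 5 for YmA against dC) among called genes with a mean of at least 2 log2 CPM and with separated libraries, the 4 members with the smallest p of each called list, and the EBF1 target genes fixed in advance. Because the fit without the block called no gene, the part of the rule that needs called genes was applied to the fit with the block, a choice made after the values were seen. It named 25 genes, of which 7 overlap another tested gene and are uncertain, since reads of overlapping genes may have been split or, without strand, mixed. Vpreb1 and Vpreb2 are near-identical copies whose reads may have been split between them.

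Tests covered 28 gene lists: EBF1 and early B-lineage targets, B-lineage transcription factors, pre-BCR and BCR signalling, V(D)J recombination, IL-7 receptor signalling, later B-cell stages, T and NK cells, NOTCH targets, myeloid cells, stem and multipotent progenitors, erythroid and mast cells, dendritic cells, stromal cells, endothelial cells and hepatocytes, the G1/S and G2/M phases, MYC-associated ribosome biogenesis, glycolysis, cholesterol biosynthesis, ribosomal proteins, mitochondrially encoded genes, interferon response, p53 targets, immediate early genes, the unfolded protein response, SWI/SNF subunits, DNA methylation and Polycomb, and adhesion. The lists overlap in part. Each was tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. Fry's mixed test asks for change in either direction. List p-values were adjusted over the 28 lists of a comparison. The fit leaves 3 residual degrees of freedom (2 with the block), the independent values from which spread is estimated. Camera with an estimated correlation and fry's test of a direction rest on these, so both have little power here. A list that they do not call is therefore not shown to be unchanged, and its call at the preset correlation is neither borne out nor refuted.

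Both altered forms were compared with the same 2 wt libraries. Correlations and overlaps between those comparisons are therefore printed beside the mean of 50 simulations of unchanged groups sharing the controls. Other settings listed in advance were RLE and upper-quartile scaling, no filter on low counts, a stricter filter (50 counts in 2 libraries), DESeq2 1.42.0, limma-voom, only the libraries of the groups compared, a minimum change of 2-fold, removal of haemoglobin, mitochondrial and immunoglobulin genes, the replicate block, and leaving out each library in turn. DESeq2 ran on the 24449 genes with any count and used its own filter, so that setting changes the filter with the tool. DESeq2 on the 14872 genes kept by edgeR's filter, the same settings of the blocked fit, and the correction for GC content and exon length with it, were added after seeing the data. Where a left-out library leaves a group with a single sample, that sample is assumed to vary like the other groups. Groups of 2 libraries are too small for a count of other splits of the samples.

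The coding of 2 tests of explanations changed after their results were seen. The test of the replicate numbers on the lists called between YmA and dC first counted a median of exactly 0 in the T and NK list as an opposite sign and so favoured the explanation. It was recoded to follow the prediction as written, which left that explanation undecided. The test of the share of B-lineage cells first used a bootstrap interval of the median and now uses the SD over the factors. Both versions placed the factors above the EBF1 targets. That cannot decide the explanation, because the factors were not checked for expression in other cells.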

Results

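The data are 6 RNA-seq libraries of sorted mouse pro-B cells, the B-lineage progenitors that depend on the transcription factor EBF1. Cells without their own Ebf1 carried wild-type EBF1, the dC form or the YmA form, with 2 libraries per group. The counts totalled 51283126 and 42978130 in replicates 1 and 2 of EBF1_wt, 46699101 and 40423508 in EBF1_dC, and 43662013 and 40975684 in EBF1_YmA. After the filter on low counts 14872 genes were tested. By the series title the study asks about phase separation in the pioneering function of EBF1, and the comparisons below ask which genes differ between cells carrying an altered form and cells carrying the wild type. Replicates of a group correlated at r = 0.956 for wt, 0.953 for dC and 0.962 for YmA over the log2 CPM of genes, which are not independent replicates. The first principal component held 44.6% of the variance and placed replicate 1 below replicate 2 in each group.

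**Figure D1:**
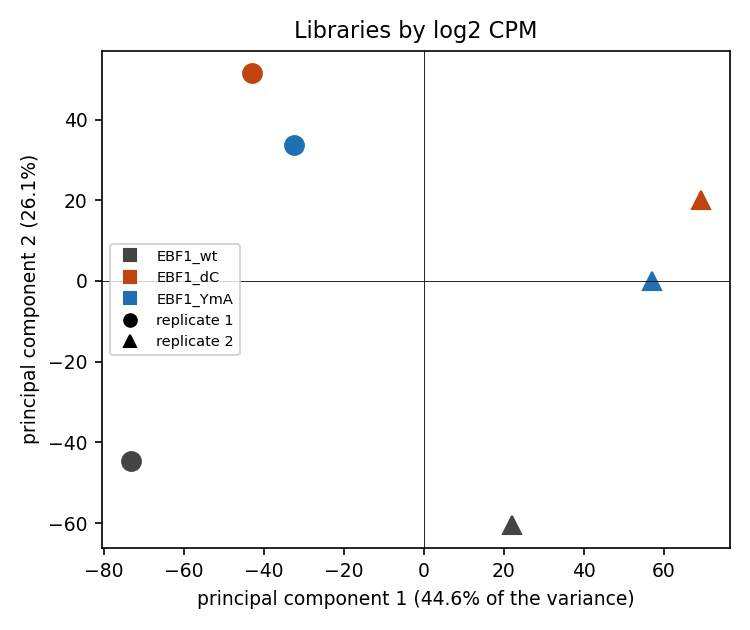
Principal components of log2 CPM over the tested genes, with a point per library, colour for the group and shape for the replicate number. The first axis (44.6% of the variance) orders the replicate numbers within every group and the second (26.1%) places both wt libraries below the dC and YmA libraries.

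Ebf1 (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091, GRCm38), the gene removed and re-expressed, was present in every library. Its level was 391.89 ± 26.05 CPM (SD, n = 2) in wt, 703.95 ± 51.88 in dC and 529.89 ± 60.32 in YmA. The dC libraries held 740.64 and 667.27 CPM, above both wt libraries at 373.47 and 410.31, and the YmA libraries held 487.24 and 572.54. These reads can come from the vector or from what is left of the locus, so they check the expression of the construct and not the deletion. Gm12158 overlaps the gene on the other strand. The log2 fold change against wt was 0.85 (SE 0.17, adjusted p = 0.39) for dC and 0.44 (SE 0.17, adjusted p = 1) for YmA, and between YmA and dC it was -0.41 (SE 0.17, adjusted p = 1), so no difference passed edgeR's test. With the replicate block the adjusted p for dC was 0.0721, and the call depended on the filter, the tool and single libraries. In blocked fits it passed without the filter on low counts (0.0238), with DESeq2 (9.34e-05, or 6.76e-05 on the filtered genes), without wt replicate 1 (0.048) and without wt replicate 2 (0.025). It did not pass without any other library, with the highest value, 0.473, and a log2 fold change of 0.68 without dC replicate 1. Without the block, DESeq2 called the difference (log2 fold change 0.85, adjusted p = 0.0162, or 0.00317 on the 14872 genes kept by the filter), as did the authors' deposited table (adjusted p = 0.00118).

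With the replicate block, the EBF1 target Cd72, the B-cell gene Ms4a1, and Car2 and Ttll11, which are in no B-lineage list, were lower in dC cells than with wild type, and Plekha7 was higher. Cd72 (chromosome 4, 43446462 to 43454628), an inhibitory co-receptor of B cells, stood at 106.71 ± 0.3 CPM (SD, n = 2) in wt and 13.94 ± 1.99 in dC. Car2 (chromosome 3, 14886273 to 14900770), a carbonic anhydrase, went from 215.35 ± 118.03 to 1.54 ± 1.49 CPM, and Ttll11 (chromosome 2, 35751241 to 35979913), of the tubulin tyrosine ligase-like family, from 59.77 ± 32.16 to 0.32 ± 0.02. Ms4a1 (chromosome 19, 11249675 to 11266241), which encodes CD20, held 268.12 and 45.08 CPM in the wt replicates and 2.05 and 0.1 in the dC replicates. Plekha7 (chromosome 7, 116123485 to 116308376), a component of adherens junctions in epithelia, rose from 2.28 ± 0.73 to 28.21 ± 0.79 CPM. All 5 changed with the replicate block (adjusted p = 0.00678 for the 4 falls and 0.0158 for Plekha7), and none of the 5 passed in edgeR without the block on the filtered genes. Without the block, DESeq2 and edgeR without the filter called all 5. The blocked calls of Car2, Ttll11, Ms4a1 and Plekha7 held without any single library.

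Among called genes with a mean of at least 2 log2 CPM and separated libraries, the remaining largest changes with the block were rises of Pcdh11x, Xylt1, Ccnd1, Inppl1, Mtcl1, Tle6, Megf10, Pcbp3 and Ski, with log2 fold changes between 2.28 for Ski and 4.50 for Pcdh11x, and falls of Nkd2, Zc3h12d, Apbb1, Smtnl2, Clic6, Clgn and Dab2ip, between -4.59 for Dab2ip and -5.76 for Nkd2. Ccnd1, which encodes cyclin D1, stood at 1.94 ± 1.94 CPM (SD, n = 2) in wt and 19.67 ± 6.43 in dC, and Apbb1 at 141.44 ± 83.62 and 3.81 ± 0.34. Pcdh11x, Xylt1, Ccnd1, Mtcl1, Ttll11 and Cd72 overlap another tested gene, so their counts are uncertain. Without dC replicate 1 the calls of Pcdh11x (adjusted p = 0.0729), Inppl1 (0.115), Ccnd1 (0.0765), Mtcl1 (0.0732), Tle6 (0.119), Megf10 (0.122), Pcbp3 (0.0574), Ski (0.114), Nkd2 (0.0729), Zc3h12d (0.0502) and Clic6 (0.112) were lost. Without dC replicate 2 those of Xylt1 (0.0559), Ccnd1 (0.105), Mtcl1 (0.0722), Tle6 (0.14), Megf10 (0.2), Pcbp3 (0.0588), Ski (0.203), Nkd2 (0.0722), Zc3h12d (0.0722) and Clic6 (0.0582) were lost.

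The list of EBF1 and early B-lineage targets fell in dC, with 21 of its 25 measured genes lower than in wt and a median log2 fold change of -0.70 (camera, adjusted p = 1.61e-07). With an estimated correlation between genes the adjusted p was 0.996. Vpreb2, a surrogate light chain gene, had 233.11 ± 103.99 CPM (SD, n = 2) in wt and 61.22 ± 0.56 in dC, and its partner Igll1 had 1574.58 ± 393.03 and 971.01 ± 25.8, while Bcar3 was higher (55.53 ± 0.32 and 123.87 ± 16.17). Reads of Vpreb2 and its near-identical copy Vpreb1 may have been split, so both are uncertain. In edgeR on the filtered genes, no member passed over all genes without the block and 2 passed as falls when adjusted over the list alone. DESeq2 and edgeR without the filter called Cd72 and Vpreb2 there, both lower. With the block edgeR on the filtered genes called 2 falls over all genes, with 23 not passing, and 1 rose and 11 fell adjusted over the list alone. Blocked DESeq2 called 1 rise and 9 falls. Of the members named in advance, Pax5, the factor that commits cells to the B lineage, had a log2 fold change of 0.12 (SE 0.30), Foxo1 -0.03 (SE 0.60), Cd79a -0.13 (SE 0.41), Cd79b -0.98 (SE 0.77), Pou2af1 -0.43 (SE 0.54), Blk -0.98 (SE 0.80) and Vpreb1 -0.76 (SE 0.31), and none passed in edgeR on the filtered genes. Cd19, on whose product the cells were sorted, was at 446 ± 9.78 CPM in wt and 229.09 ± 135.77 in dC (log2 fold change -0.96, SE 0.52), also not called there, though blocked DESeq2 called Cd19 and Cd79b as lower. Cd19 is itself in the target list, and only cells positive for CD19 were sorted. The values of every group therefore describe cells that kept this marker and not all transduced cells.

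The list of pre-BCR and BCR signalling, which shares members with the target list, fell as well. Of its 29 genes 25 were lower, the median log2 fold change was -0.40 and the adjusted p was 6.79e-08, or 0.996 with an estimated correlation. Plcg2, the phospholipase downstream of the receptor, stood at 364.37 ± 27.7 CPM (SD, n = 2) in wt and 242.15 ± 24.79 in dC. Over all genes edgeR on the filtered genes called 0 members without the block and 1 fall with it, while DESeq2 and edgeR without the filter called Cd72 and Vpreb2 without the block. The calls of both B-lineage lists held without any single library (highest adjusted p 0.0184). Among markers of other cells, the stromal list rose (7 measured genes, 5 higher, median 0.50, adjusted p = 0.00265), but its adjusted p was 0.0971 with the replicate block and 0.935 with an estimated correlation. Its most abundant member Igfbp4 had 43.43 ± 9.73 CPM in wt and 121.13 ± 4.84 in dC, Sparc had 0.14 ± 0.17 and 2.84 ± 0.77, Serpinf1 was lower in dC (7.32 ± 3.18 and 2.12 ± 2.08), and Fn1 (0 counts in wt, 29 and 4 in the dC replicates) was at least 11.6-fold higher. That bound rests mostly on dC replicate 1.

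The other 25 lists were not called for dC against wt. The adjusted p was 0.952 for the B-lineage transcription factors, later B-cell stages, G2/M genes, p53 targets, SWI/SNF subunits and the DNA methylation and Polycomb list. It was 0.793 for V(D)J recombination, NOTCH targets, the erythroid and mast cell list and G1/S genes, and 0.684 for the T and NK, glycolysis, ribosomal protein and interferon lists. IL-7 receptor signalling and adhesion had 0.877, and progenitor and immediate early genes 0.66. The values were 0.593 for mitochondrially encoded genes, 0.596 for the endothelial and hepatocyte list, 0.676 for myeloid genes, 0.695 for MYC-associated ribosome biogenesis, 0.975 for dendritic cells, 0.982 for cholesterol biosynthesis and 0.983 for the unfolded protein response. Median, mean and direction of the test had the same sign for every called list of the 3 comparisons, and did not for 6 of the uncalled lists here, 4 for YmA against wt and 3 for YmA against dC.

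For single genes, edgeR called 0 of 14872 for dC against wt (smallest adjusted p 0.0834). At an unadjusted p under 0.05 there were 773 genes, 346 higher and 427 lower. Limma-voom called 0 on these genes. DESeq2 called 259 (104 higher and 155 lower) of the 24449 genes with any count. It called 255 on the 14872 genes kept by the filter, a setting added after seeing the data. A separate edgeR fit without the filter called 205 of the 24449 genes, which need not be the genes that DESeq2 called. With the replicate block edgeR called 142, of which 52 rose and 90 fell, and 107 of the 140 that the authors' deposited table lists were called the same way there, where 231 genes in all are called. The blocked count was 436 without wt replicate 1, 588 without wt replicate 2, 270 without YmA replicate 1 and 277 without YmA replicate 2. It dropped to 22 without dC replicate 1 (22 of them among the 142) and to 28 without dC replicate 2 (25 among the 142).

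**Figure D2:**
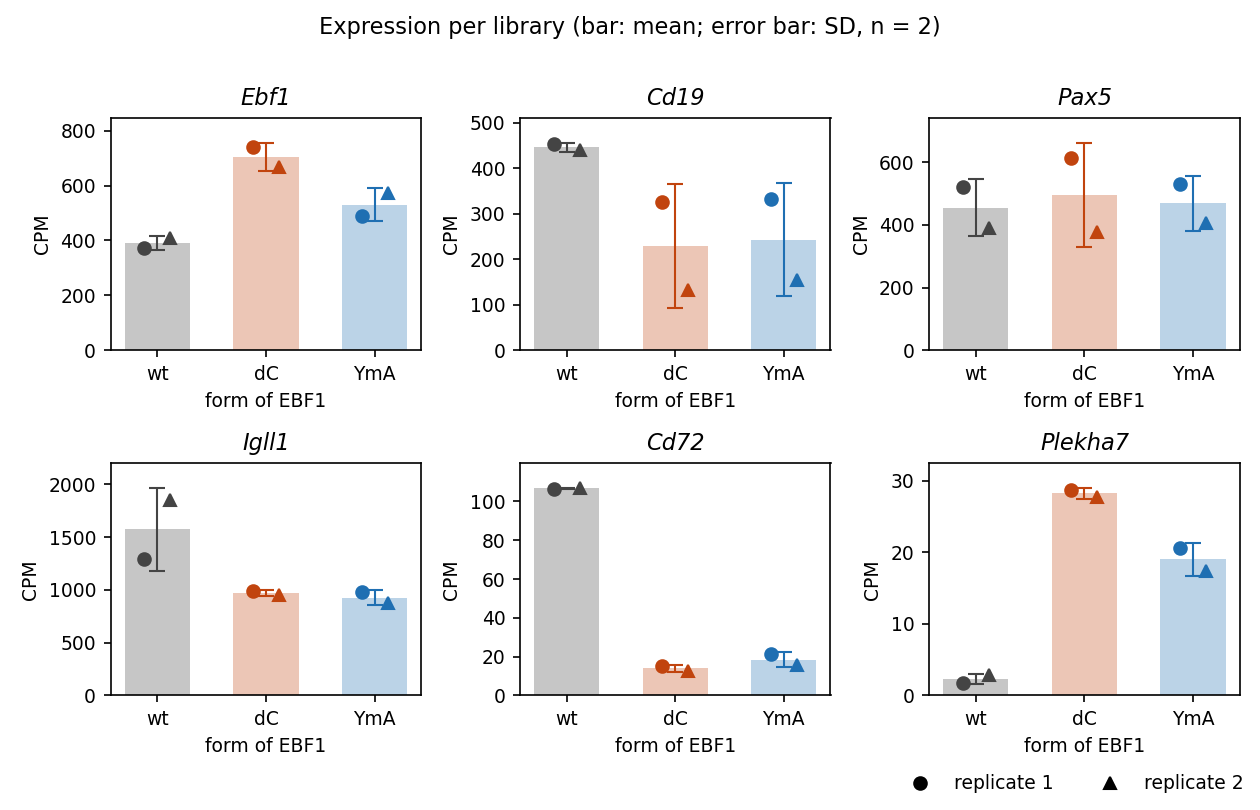
CPM of Ebf1, Cd19, Pax5, Igll1, Cd72 and Plekha7 in the 3 groups, with bars for the mean, error bars for the SD (n = 2), circles for replicate 1 and triangles for replicate 2. Cd72 is at 106.71 CPM in wt against 13.94 in dC and 18.38 in YmA, while Pax5 overlaps between the groups.

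With the replicate block, Cd72, Ms4a1 and genes of other functions were lower in YmA cells than with wild type, and Plekha7 and Mtcl1 were higher. Cd72 fell from 106.71 ± 0.3 CPM (SD, n = 2) in wt to 18.38 ± 3.97, Akap12 (chromosome 10, 4266380 to 4359470), a scaffold protein of protein kinase A, from 213.15 ± 1.53 to 56.53 ± 7.72, and Car2 from 215.35 ± 118.03 to 8.84 ± 8.57. Tmprss3, a transmembrane serine protease (chromosome 17, 31179265 to 31198977), fell from 46.92 ± 5.99 to 6.45 ± 0.73 CPM and Ms4a1 from 156.6 ± 157.71 to 3.17 ± 3.88. Plekha7 rose from 2.28 ± 0.73 to 18.99 ± 2.3 CPM and Mtcl1 from 2.05 ± 0.38 to 12.93 ± 1.19. Falls of Ttll11, Apbb1, Fam129c, Smtnl2 and Amotl1 completed the genes named with the block, with log2 fold changes between -2.86 for Amotl1 and -3.78 for Ttll11. Fam129c, Cd72, Ttll11 and Mtcl1 overlap another tested gene and are uncertain. All of these were called with the replicate block (adjusted p from 0.0347 to 0.0477) and none by edgeR on the filtered genes without it. Without the block, edgeR without the filter called all of them, and DESeq2 all but Ms4a1. The call of Mtcl1 was lost without dC replicate 1 (0.053), dC replicate 2 (0.0501) or YmA replicate 1 (0.0658), that of Amotl1 without YmA replicate 1 (0.0597) and that of Smtnl2 without YmA replicate 2 (0.0523).

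The EBF1 target list fell in YmA with 22 of 25 genes lower (median log2 fold change -0.70, camera, adjusted p = 5.01e-09, or 0.602 with an estimated correlation). Gfra2, which encodes a receptor for GDNF-family ligands, had 269.56 ± 13.1 CPM (SD, n = 2) in wt and 60.35 ± 28.17 in YmA, and Vpreb2 had 233.11 ± 103.99 and 92.88 ± 29.7. In edgeR on the filtered genes, 0 members passed over all genes without the block and 1 fell adjusted over the list alone, while DESeq2 and edgeR without the filter called Cd72 and Gfra2 as lower. With the block 1 fell over all genes, and 1 rose and 6 fell adjusted over the list alone. The pre-BCR and BCR signalling list fell too (26 of 29 lower, median -0.45, adjusted p = 5.01e-09, or 0.838 with an estimated correlation), with Pik3r1 at 177.26 ± 19.11 CPM in wt and 129.48 ± 8.8 in YmA. Both calls held without any single library (highest adjusted p 0.00423 and 0.0209). Of the genes named in advance, Igll1 had a log2 fold change of -0.76 (SE 0.22), Vpreb1 -0.85 (SE 0.31), Cd79a -0.32 (SE 0.41), Cd79b -0.72 (SE 0.77), Pou2af1 -0.31 (SE 0.54), Foxo1 -0.15 (SE 0.60), Blk -1.12 (SE 0.80) and Pax5 0.04 (SE 0.30), and Cd19 had -0.88 (SE 0.52). None of these passed in edgeR on the filtered genes, and blocked DESeq2 called Igll1, Vpreb1, Cd79b and Cd19 as lower.

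The lists of ribosomal proteins, MYC-associated ribosome biogenesis and the stress response were called as higher in YmA at the preset correlation and were not called at an estimated correlation (adjusted p = 0.838 for each). In each of them edgeR on the filtered genes called no member over all genes, with or without the block, while blocked DESeq2 called 6 rises in the stress response and 1, Odc1, in the MYC-associated list. Adjusted over the list alone, edgeR called 7 rises in the stress response with the block and 0 without it. All 36 ribosomal protein genes were above wt (median log2 fold change 0.22, adjusted p = 2.45e-04), for instance Rplp0 at 1010.5 ± 201.55 CPM (SD, n = 2) in wt and 1204.85 ± 25.02 in YmA. All 30 genes of MYC-associated ribosome biogenesis were higher (median 0.20, adjusted p = 0.00772), for instance the polyamine enzyme Odc1 at 71.06 ± 28.93 and 128.28 ± 56.88. The median of this list was -0.013 within replicate 1 and 0.402 within replicate 2. The unfolded protein and integrated stress response list rose with 15 of 24 higher (median 0.40, adjusted p = 0.0158), including Chac1, a target of the stress response, at 11.66 ± 7.7 and 35.66 ± 6.13 CPM, Sesn2 and Psat1. All 3 calls were lost without wt replicate 1 or YmA replicate 2. Without wt replicate 1 the adjusted p was 0.586 for ribosomal proteins, 0.275 for MYC-associated genes and 0.677, with the direction turned, for the stress response. Without YmA replicate 2 it was 0.268, 0.34 with the direction turned, and 0.454.

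Lower lists in YmA included the interferon response (18 of 22 lower, median -0.49, adjusted p = 2.82e-04, or 0.602 with an estimated correlation), with Ly6e at 782.25 ± 210.35 CPM (SD, n = 2) in wt and 441.08 ± 106.28 in YmA, Ddx58 at 9.5 ± 3.32 and 3.98 ± 0.67, and Oas3 (67 and 27 counts in wt replicates 1 and 2, 0 counts in YmA) at least 29-fold lower. The call of the interferon list held without any single library. The T, NK and innate lymphoid list fell (15 of 21 lower, median -0.68, adjusted p = 0.0147, or 0.838 with an estimated correlation), and without wt replicate 2 its adjusted p was 0.501. Its median was -0.235 with the replicate block (adjusted p = 0.00291). Its member Gzma was at 8.92 ± 11.2 CPM in wt and had 0 counts in YmA, at least 237-fold lower. That bound rests mostly on wt replicate 2 (718 counts against 50 in replicate 1). Gzma had 0 counts in both dC libraries as well, so its fall is not particular to YmA. Another member, Notch1, was at 44.34 ± 7.49 and 27.59 ± 4.33. G2/M genes fell slightly (28 of 32 lower, median -0.13, adjusted p = 0.0403, or 0.838 with an estimated correlation), as in Kif11 at 480.67 ± 80.11 and 377.85 ± 66.99 CPM. The median of the G2/M list was 0.012 within replicate 1 and -0.312 within replicate 2. With the block its adjusted p was 0.031, and after the correction for GC content and length 0.0989. The call without the block was lost without wt replicate 2 (0.364), YmA replicate 2 (0.805), dC replicate 1 (0.0557) or dC replicate 2 (0.072). The stromal list rose (4 of 7 higher, median 0.24, adjusted p = 0.00329, or 0.602 with an estimated correlation), with Igfbp4 at 99.89 ± 21.93 CPM against 43.43 ± 9.73 in wt. Its median was 1.66 within replicate 1 and -0.05 within replicate 2. It was lost without wt replicate 1 (0.222) or wt replicate 2 (0.0572).

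The other 19 lists were not called for YmA against wt (lowest adjusted p 0.0629). With the block, later B-cell stages (0.00185) and V(D)J recombination (0.031) were called as well, both lower. Neither held with an estimated correlation (0.74 for each), and V(D)J recombination was not called after the correction for GC content and length (0.0989). For single genes, edgeR called 0 of 14872 (smallest adjusted p 0.226), with 568 at an unadjusted p under 0.05, 246 higher and 322 lower. Limma-voom called 0 on these genes. DESeq2 called 124 of the 24449 genes with any count and 126 on the 14872 kept by the filter. A separate edgeR fit without the filter called 67 of the 24449. With the replicate block edgeR called 18, of which 3 rose and 15 fell, and 13 of them were called the same way in the authors' deposited table, which calls 97. The blocked count was 242 without wt replicate 1, 517 without wt replicate 2 and 42 without YmA replicate 2. It was 10 in a fit of only the 4 libraries compared, where Akap12, Amotl1, Fam129c, Smtnl2 and Ttll11 (adjusted p = 0.0558), Plekha7 (0.0681) and Mtcl1 (0.0789) were no longer called.

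With the block all 18 genes that edgeR called for YmA were also called for dC, 3 rising and 15 falling. The overlap was not complete in every setting. DESeq2 called 101 of its 124 YmA genes for both forms (381 of 552 with the block), and edgeR without the filter 60 of 67 (124 of 140 with the block). Simulated unchanged groups sharing the wt libraries gave a mean overlap of 0.02 genes in each direction. They called means of only 0.16 and 0.22 rising and 0.32 and 0.36 falling genes, so that overlap cannot gauge the 18 shared calls. Independent lists of these lengths would share 0.0105 rising and 0.0908 falling genes, which ignores the shared controls. At edgeR's unadjusted p under 0.05 with the block, 482 rises and 572 falls were shared. The simulations, with fewer such calls, shared means of 90.7 and 61.6. Across the tested genes, which are not independent replicates, the log2 fold changes of dC and YmA against wt correlated at 0.759 (Pearson) and 0.711 (Spearman), where the simulated groups gave 0.496 and 0.459. The covariance was 0.708 against 0.275 in the simulation, a difference of 0.433. The controls were not split between the forms, so part of the excess may come from the shared controls. Without a library of an altered form the Pearson correlation was between 0.543 and 0.601. Of the 142 genes called for dC, 141 had the same direction in YmA and 130 had the larger change in dC. As many genes of simulated unchanged groups, taken by the smallest p for dC, gave means of 128.8 (121 to 137 over 50 simulations) and 128.7 (121 to 135), so the first count lies above that range and the second within it. Of the 18 genes called for both forms, 16 had the larger change in dC, with Cnn1 and Akap12 as the exceptions.

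**Figure D3:**
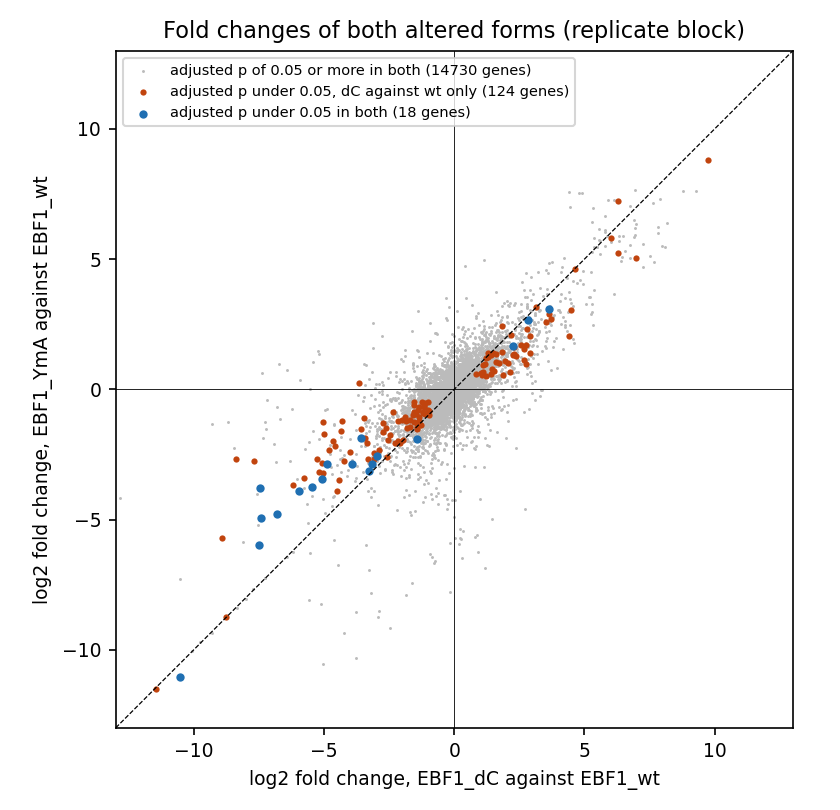
Log2 fold changes against wt with the replicate block, dC on the x axis and YmA on the y axis, with a point per tested gene. Orange points are called for dC alone and blue points are the 18 genes called for both forms, most of which lie closer to 0 on the YmA axis than the dashed line of equality.

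Compared directly, YmA and dC cells did not differ detectably in the EBF1 target and pre-BCR lists at either correlation. The 9 lists called at the preset correlation were of metabolism, protein synthesis, stress, proliferation, interferon response and 2 groups of markers of other cells, the T and NK list and the endothelial and hepatocyte list, and none was called at an estimated correlation. The EBF1 target list had 12 genes higher and 13 lower in YmA (median log2 fold change -0.06, camera, adjusted p = 0.908), and the pre-BCR list 15 higher and 14 lower (adjusted p = 0.859). These p-values do not show that the forms act alike. Members of the glycolysis list were higher in YmA (20 of 23, median 0.28, adjusted p = 1.57e-04), such as Pfkp at 29.45 ± 7.14 CPM (SD, n = 2) in dC and 44.53 ± 1.2 in YmA. Bnip3, a list member that is not a glycolytic enzyme, had 63.19 ± 30.9 and 121.78 ± 25.68 CPM. Ribosomal protein genes were higher in all 36 cases (median 0.16, adjusted p = 1.92e-04), as in Rps18 at 781.72 ± 111.75 and 888.88 ± 13.58 CPM. The unfolded protein and integrated stress response list was higher (18 of 24, median 0.31, adjusted p = 2.69e-04), with Nupr1 at 6.15 ± 3.65 and 14.45 ± 1.37, and so was MYC-associated ribosome biogenesis (30 of 30, median 0.15, adjusted p = 0.0112), with Myc at 512.54 ± 71.62 and 595.52 ± 132.44. With an estimated correlation the adjusted p was 0.876 for each of these 4 lists.

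Interferon response genes were lower in YmA than in dC (18 of 22, median -0.43, adjusted p = 1.57e-04, or 0.56 with an estimated correlation), such as Stat1 at 15.81 ± 0.47 CPM (SD, n = 2) in dC and 11.47 ± 0.95 in YmA. G2/M genes were lower in all 32 cases (median -0.10, adjusted p = 0.00817), as in Bub1b at 449.95 ± 5.19 and 388.86 ± 21.21 CPM, and cholesterol biosynthesis genes in 22 of 24 (median -0.10, adjusted p = 0.0276), as in Hsd17b7 at 33.28 ± 1.34 and 26.36 ± 0.05. T, NK and innate lymphoid genes were lower (17 of 21, median -0.41, adjusted p = 0.0164, or 0.304 with the replicate block), with Nkg7 at 63.6 ± 20.99 and 17.24 ± 6.48 CPM, while Lat was higher. For these last 3 lists the adjusted p was 0.876 with an estimated correlation. The endothelial and hepatocyte list (adjusted p = 6.38e-04, or 0.56 with an estimated correlation) rested on 3 measured genes, Pecam1, Kdr and Apoa2, of which Kdr and Apoa2 were under 1 CPM. The other 19 lists were not called (lowest adjusted p 0.0502, for adhesion, which was called with the block at 0.00287 as lower, or 0.86 with an estimated correlation).

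None of the 9 list calls between YmA and dC held without every single library. Without dC replicate 1 the adjusted p was 0.67 for glycolysis, 0.239 for ribosomal proteins, 0.87 for the stress response, 0.0729 for MYC-associated genes and 0.845 for cholesterol biosynthesis, all with the direction turned, and 0.762 for G2/M and 0.239 for the endothelial list. Without YmA replicate 2 it was 0.344 for glycolysis, 0.715 for ribosomal proteins, 0.467 for the stress response, 0.879 for G2/M, 0.893 with the direction turned for cholesterol biosynthesis, 0.0652 for the T and NK list, and MYC-associated genes passed in the opposite direction (0.0266). Without dC replicate 2 the interferon list had 0.0614 and the T and NK list 0.901 with the direction turned, and without YmA replicate 1 the T and NK list had 0.0611. For single genes, edgeR called 0 of 14872 between YmA and dC (smallest adjusted p 1), with 151 at an unadjusted p under 0.05, and 0 with the replicate block (smallest adjusted p 0.19, 483 unadjusted). Limma-voom called 0 on these genes. DESeq2 called 8 of the 24449 genes with any count and 8 on the 14872 kept by the filter. A separate edgeR fit without the filter called 4 of the 24449.

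**Figure D4:**
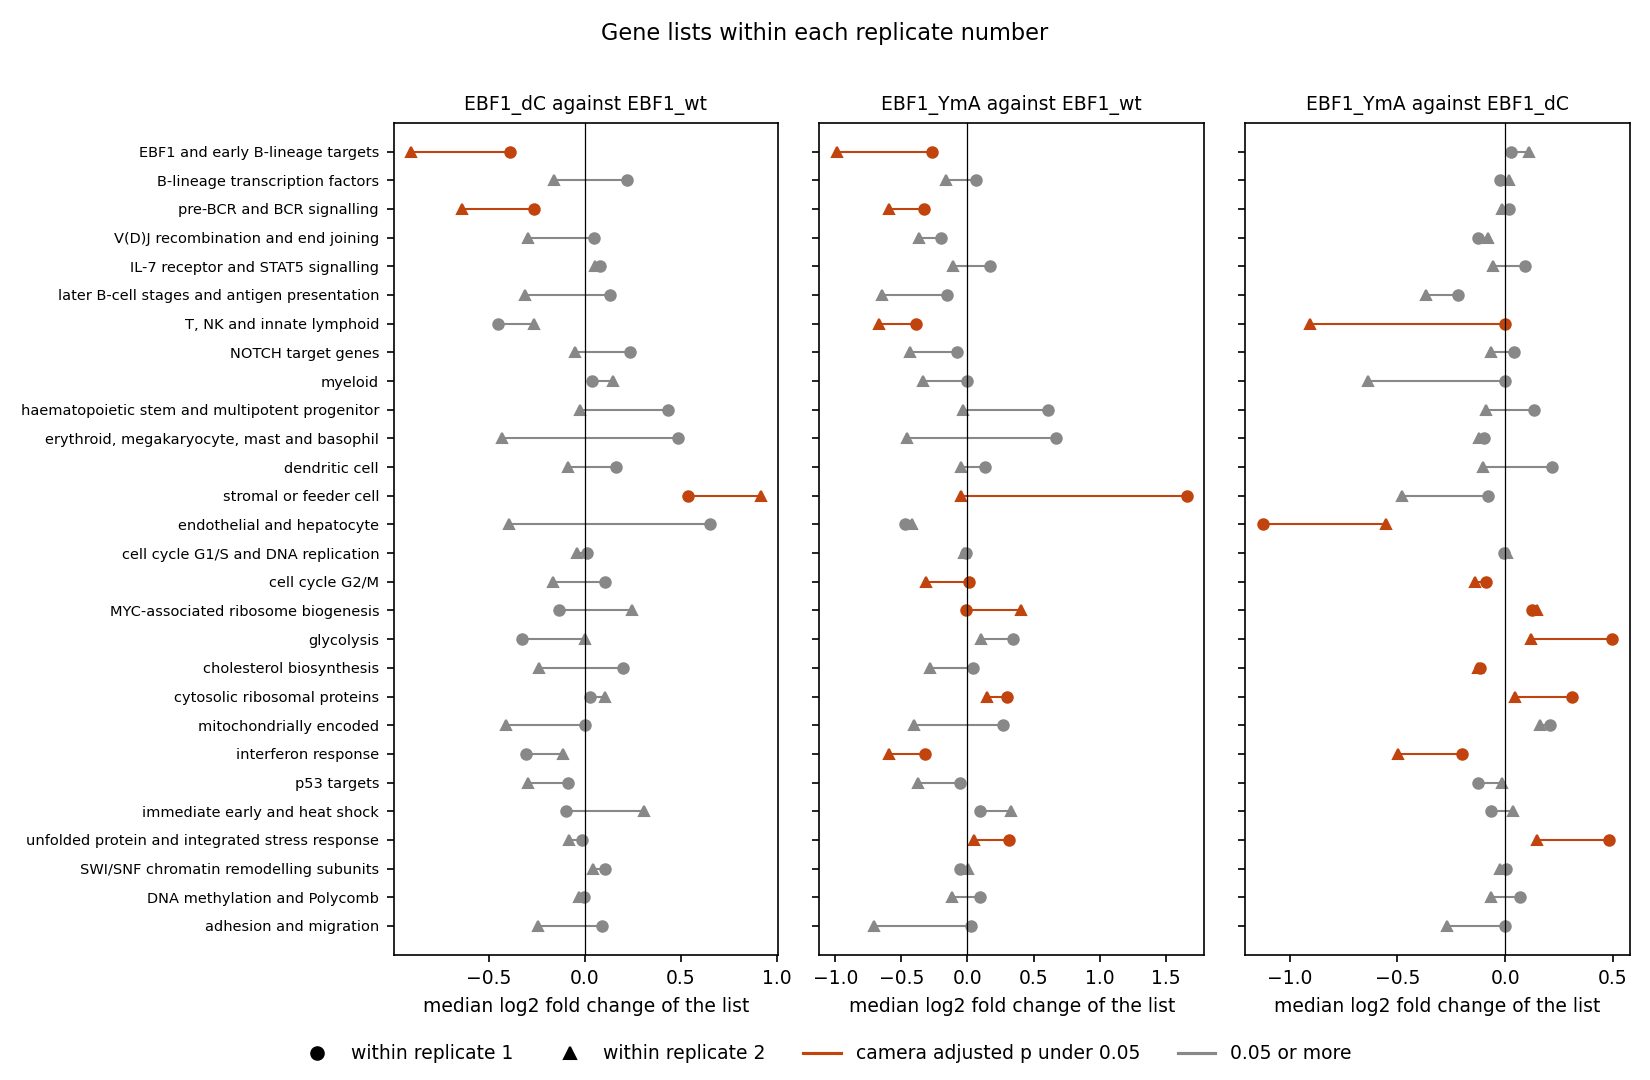
Median log2 fold change of each gene list within replicate 1 and within replicate 2, with a panel per comparison (the x axes differ) and orange for lists with a camera adjusted p under 0.05. The EBF1 target and pre-BCR lists lie below 0 in both replicates for dC and for YmA against wt, and near 0 for YmA against dC.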

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

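Of the tests below, those on GC content and length, on the level of Ebf1 and on the share of B-lineage cells were chosen after the result they measure was seen, and the tests on depth and within replicate numbers were written before it.

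In the direct comparison of YmA with dC, camera called 9 gene lists at the preset correlation, by a test of the difference itself. Higher in YmA were glycolysis (adjusted p = 1.57e-04), ribosomal proteins (1.92e-04), the unfolded protein and integrated stress response (2.69e-04) and MYC-associated ribosome biogenesis (0.0112). Lower were interferon response (1.57e-04), the endothelial and hepatocyte list (6.38e-04), G2/M genes (0.00817), the T and NK list (0.0164) and cholesterol biosynthesis (0.0276). None held with an estimated correlation between genes, and each was lost or turned without some single library. The T and NK list was not called with the replicate block (camera, adjusted p = 0.304).

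For these lists, a bias by GC content or gene length is argued against, since the 8 of these 9 lists that were called with the replicate block were all still called after the trends with both were removed (8 of 8, highest adjusted p 0.00962), as was adhesion, called only with the block (0.00268). A deviation of the libraries of a single replicate number remains open and cannot be told apart from a difference between the forms, for the T and NK list at least: 8 of the 9 medians had the same sign in both replicates, but that list's median was 0 in replicate 1 and -0.904 in replicate 2. With 2 numbers, equal signs alone are weak evidence, and sizes differed, as in ribosomal proteins at 0.31 in replicate 1 and 0.04 in replicate 2. Glycolysis, ribosomal proteins, the stress response and MYC-associated genes also rose from replicate 1 to replicate 2 across the groups (adjusted p = 4.91e-06, 2.83e-07, 3.7e-06 and 5.2e-09, none with an estimated correlation), so a chance difference in culture state may account for part of the pattern. A difference between the forms is a further open explanation.

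The EBF1 target and pre-BCR lists were lower in dC and in YmA, each measured against the same 2 wt libraries, so the likeness of the forms is in part built in. The share of B-lineage cells in the sort stays open, because the factors used to test it were not checked for expression in other cells. The median log2 fold change of the 22 factors outside the target list was 0.035 in dC (SD over factors 0.578) and -0.017 in YmA (SD 0.561). For the targets it was -0.697 and -0.698. Of all 26 factors, 13 were higher and 13 lower in dC, and 11 and 15 in YmA. With the block Ikzf3 (-1.63 in dC and -1.52 in YmA) and Spib (-1.18 and -1.64) were lower but uncalled. The stromal list rose in both forms at the preset correlation, while the T and NK list did not. A lower level of Ebf1 reads as a whole is argued against by their log2 fold changes with the replicate block, 0.849 (SE 0.141) in dC and 0.434 (SE 0.14) in YmA. Reads of the vector could not be told apart from those of what is left of the locus, and protein was not measured. The rise in dC was itself not called by edgeR with the block (adjusted p = 0.0721). A GC or length bias and a deviation of the libraries of a single replicate number are argued against as the whole cause, since 4 of the 4 list calls remained after the correction (highest adjusted p 1.8e-10) and 4 of the 4 medians lay below 0 within both replicates (closest to 0, -0.265), which over 2 numbers is weak evidence, with larger falls in replicate 2 (-0.903 against -0.39 for the targets in dC and -0.988 against -0.268 in YmA). The lists share members and both comparisons share the wt libraries, so these 4 results are not separate. Correlation between the genes of a list stays open (adjusted p of 0.996, 0.602 and 0.838 with an estimated correlation). So does a deviation of the shared wt libraries, which was not tested. A part for culture state stays open too, since both lists also fell from replicate 1 to replicate 2 across the groups. Camera's adjusted p for that fall was 0.00642 and 1.55e-06, and 0.788 for each with an estimated correlation. A weaker action of the altered forms on these genes is a hypothesis that was not tested.

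Many genes differed between replicates 1 and 2 in the same way in the 3 groups: 1600 were called in the fit with the block, 835 higher and 765 lower in replicate 2. A bias by GC content or length is argued against as the whole cause, since 1898 genes were called after its removal, 1479 of them shared with the 1600, and both properties explained 0.74% of the variance of the shift. The difference in depth is argued against too, since 1615 genes were called after every library was thinned to the smallest total, 1565 of them shared. The design names no group that separates the numbers, so no biological explanation was tested, and a shared day, litter or sort stays open because the labels give none.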

How the results depend on the processing

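The fit with the replicate block and DESeq2 on all genes with counts were among the settings listed in advance, while DESeq2 on the filtered genes and every other setting of the blocked fit were chosen after seeing the data.

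The fit without the block called 0 genes in each comparison under RLE or upper-quartile scaling, the stricter filter, limma-voom, the libraries of the compared groups alone, the removal of haemoglobin, mitochondrial and immunoglobulin genes and each left-out library. Without a filter on low counts it called 205 genes for dC, 67 for YmA and 4 for YmA against dC, with 60 called for both forms and a correlation of their fold changes of 0.591 in place of 0.759, over the added genes with few counts. DESeq2 called 259, 124 and 8, with 101 for both forms, and Ebf1 was called for dC with a log2 fold change of 0.85, on 24449 genes without edgeR's filter. On the 14872 genes kept by that filter DESeq2 called 255, 126 and 8, with 103 for both forms and Ebf1 at 0.85, so DESeq2 changed little with the filter while edgeR's calls appeared only without it. The replicate block gave 142, 18 and 0 calls, with 18 for both forms. Apart from the list calls named beside each comparison, it changed no other list call of camera. Calls of fry's mixed test and of members adjusted over a list alone did change with it. The cause of edgeR's dependence on the filter was not tested.

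Within the blocked fit RLE scaling, upper-quartile scaling, the stricter filter, limma-voom and the removed gene classes gave 142 to 183 calls for dC, 18 to 20 for YmA and 0 for YmA against dC. No filter gave 340, 140 and 3 calls, 124 for both forms and a correlation of 0.591. DESeq2 gave 698, 552 and 58, with 381 for both forms, and on the filtered genes 713, 563 and 56, with 391 for both forms. The libraries of the compared groups alone gave 228 for dC and 10 for YmA, with 10 for both forms, from fewer samples. Leaving out single libraries gave 22 to 588 calls for dC, 22 to 517 for YmA, 0 to 5 for YmA against dC and 16 to 376 for both forms, where the lone sample of a group is assumed to vary like the others. The correlation ranged from 0.543 to 0.852 without the block and from 0.522 to 0.841 with it.

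With an estimated correlation or with fry's test of a direction, 0 lists were called for dC against wt, 0 for YmA against wt and 0 for YmA against dC. Both tests have little power with so few residual degrees of freedom, so these counts cannot decide the calls at the preset correlation. Fry's mixed test called 4, 0 and 0, and 15, 7 and 1 with the block. Leaving out single libraries gave 3 to 8, 5 to 14 and 5 to 14 called lists. List adjusted p with a turned direction for some library ranged, for YmA against dC, from 0.00184 to 0.893 for cholesterol biosynthesis, 3.85e-11 to 0.715 for ribosomal proteins, 3.85e-11 to 0.67 for glycolysis, 3.35e-10 to 0.0729 for MYC-associated genes, 1.6e-04 to 0.901 for T and NK genes and 1.26e-07 to 0.87 for the stress response. For YmA against wt they ranged from 1.88e-09 to 0.34 for MYC-associated genes and from 3.92e-05 to 0.677 for the stress response.

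Among named genes and called lists no direction turned outside left-out libraries. Of all 84 list results, 5 turned with the block, all uncalled in both fits (lowest adjusted p 0.802). Among uncalled genes, log2 fold changes of YmA against dC ranged from -1.978 to 0.634 for Blk, -0.561 to 0.87 for Cd19, -0.675 to 0.325 for Cd79a, -0.627 to 1.672 for Cd79b, -0.655 to 0.747 for Foxo1, -0.145 to 0.007 for Igll1, -0.033 to 0.427 for Myc, -0.384 to 0.314 for Pax5, -1.318 to 0.229 for Pecam1, -0.037 to 0.483 for Polr1a, -0.229 to 0.595 for Polr1b, -0.421 to 0.988 for Pou2af1 and -0.054 to 0.488 for Wdr12. Those of dC against wt ranged from -0.643 to 0.244 for Cd79a, -0.896 to 0.607 for Foxo1, -0.272 to 0.427 for Pax5 and -1.302 to 0.108 for Pou2af1. Those of YmA against wt ranged from -0.804 to 0.044 for Cd79a, -0.686 to 0.488 for Foxo1, -0.16 to 0.272 for Pax5, -0.789 to 0.095 for Pou2af1 and -0.075 to 0.945 for Srm. Every library held 40423508 counts or more. The cause of the turns was not tested.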

Other observations

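All genes and tests of this part were chosen after their values were seen, and none is a test of an explanation.

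Cnn1, Tnnt2, Tnni2 and Myl4 were picked by hand from the 90 genes that fell in dC with the block, and no test of a shared function was run. Cnn1 (calponin, chromosome 9, 22099216 to 22109630) had 33.52 and 85.2 CPM in the wt replicates, 0.06 and 0 in dC and 0.04 and 0 in YmA. Tnnt2, a troponin T of heart muscle, stood at 30.68 ± 15.06 CPM (SD, n = 2) in wt, 0.09 ± 0.05 in dC and 5.44 ± 4.51 in YmA. Tnni2, a troponin I of skeletal muscle, had 34.29 ± 6.47, 5.12 ± 0.54 and 10.92 ± 3.97 CPM, and the myosin light chain Myl4 26.42 ± 11.63, 5.05 ± 3.72 and 7.89 ± 6.48. With the replicate block the adjusted p for dC against wt was 0.00919 for Cnn1, 0.00678 for Tnnt2, 0.0389 for Tnni2 and 0.0369 for Myl4. Without the block none passed (0.127, 0.209, 0.214 and 0.814). For YmA against wt with the block Cnn1 passed (0.0347), and Tnnt2 (0.0595), Tnni2 (0.169) and Myl4 (0.12) did not.

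Cd34 and Cd9 were higher in dC, while the fixed list of stem and multipotent progenitors was not called (12 of 21 genes higher, adjusted p = 0.66, or 0.323 with the block). Cd34 (chromosome 1, 194938819 to 194961279), a marker of early progenitors, had 0 and 0.19 CPM in the wt replicates, 7.76 and 15.2 in dC and 3.05 and 2.36 in YmA (adjusted p = 0.041 for dC and 0.144 for YmA with the block, 0.302 and 0.987 without). The tetraspanin Cd9 had 6.23 ± 1.14 CPM (SD, n = 2) in wt, 27.17 ± 5.18 in dC and 9.92 ± 3.05 in YmA, with a log2 fold change of 2.12 for dC (adjusted p = 0.019 with the block and 0.225 without). Csf2rb, the shared receptor chain for IL-3 and GM-CSF, was lower in dC with the block (log2 fold change -0.97, adjusted p = 0.0432). In YmA it did not pass (-0.97, 0.0987), and without the block neither form passed (adjusted p = 1 for both).

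Between replicate numbers, Cd22 held 185.28, 109.64 and 114.28 CPM in replicate 1 of wt, dC and YmA and 8.28, 2.42 and 5.57 in replicate 2, and Spib 312.9, 291.14 and 209.69 against 99.72, 23.93 and 17.39. Il2ra went the other way, with 3.75, 6.02 and 9.51 CPM in replicate 1 and 45.38, 64.37 and 18.04 in replicate 2. Across lists, later B-cell stages were lower in replicate 2 (adjusted p = 6.95e-13, or 0.598 with an estimated correlation).

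Summed over the measured members of the stromal list, levels were 43.0 and 63.3 CPM in wt, 129.3 and 128.7 in dC and 120.7 and 92.6 in YmA, with Igfbp4 the most abundant. Igfbp4 alone held 36.55 and 50.31 CPM in wt and 124.55 and 117.71 in dC, so the sums mostly reflect this gene. Of the 7 measured members, 5 were higher and 2 lower in dC than in wt. Summed T and NK genes were 142.1 and 332.3 CPM in wt, 209.5 and 315.2 in dC and 154.9 and 152.7 in YmA. The sort on CD19 would remove most stromal and T cells, and the lists were fixed before the data were examined.

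Of the 142 genes called for dC with the block, 22 had another gene called in the same direction within 500 kb. In 10000 draws of genes matched on expression the mean was 9.8 and the highest 28, and 75 draws reached the observed number (permutation p = 0.0076, 1-sided). Gene density was not matched. The neighbours include Cnn1 with Elof1 and Acp5 on chromosome 9, Dab2ip with Ttll11 on chromosome 2, Asb2 with Otub2 on chromosome 12, and Tnfrsf1a with Cd9 on chromosome 6.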
